A study of Homo sapiens with 6 samples.

How the data were processed

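Whole colon tissue from 3 patients was dissociated, cryopreserved and profiled with the 10x Genomics 3' version 3 droplet assay, per the labels' protocols. A pathologist's histochemical reading separated the segment labelled healthy from the segment labelled aganglionic, and the patient number in the labels pairs the samples. The deposited values are raw UMI counts per gene and barcode, 1 matrix per library. The authors made these counts with Cell Ranger 3.1.0 (patients 1 and 2) and 5.0.0 (patient 3), per the file headers, so the version is confounded with the patient and not with the state. GRCh38 is named in the submitters' processing notes. The annotation release and the settings for calling cells are not given in the sources used here. In each matrix, 48 features with a duplicated symbol were kept as separate features. Gene positions were taken from a GRCh38 annotation by gene ID. Where 3' tags of near-identical genes overlap (immunoglobulin constant genes, HLA genes, metallothioneins), their counts are uncertain.

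Cells with at least 300 detected genes and at most 25% mitochondrial UMIs were kept, 26007 of 41393 barcodes. Scrublet, run per library in scanpy 1.11.5, found no usable automatic threshold in 4 libraries, so a score limit of 0.25, chosen after seeing the scores, was used in all. It removed 398 cells (1.53%), and 25609 were retained. Counts were scaled to 10000 per cell and log-transformed, 3000 variable genes and 30 principal components were taken, and cells were clustered with 15 neighbours by Leiden at resolution 1.5 (leidenalg 0.10.2, igraph 0.11.9, random seed 0). The clustering joined all libraries without batch correction, and it used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. Clusters were named from 28 marker lists: at least 3 markers detected in a share of at least 0.2 of the cells and over log2 fold 1 above the other cells, and top 10 genes not led by another class. Clusters with over 50% doublets, led by cell cycle genes, or with no marker among the top 10 genes and under 50% of the markers detected, were also left unnamed. The naming rules were tightened once, after a first pass had called cluster 5 smooth muscle and before any test between groups. Of 42 clusters, 10 stayed unnamed and the others formed 16 classes. Clusters shown by number were picked after the data were seen.

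Cells are not replicates, so UMI counts were summed per sample, and per sample and class where each library held at least 20 cells. Differences between 3 healthy and 3 aganglionic samples were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM, filterByExpr, Benjamini-Hochberg adjustment, threshold 0.05), and log2 values are aganglionic minus healthy with the standard error of the fit, not given for log2 values within 0.01 of 0, where it was numerically unstable between reruns. Class abundance was tested with the same tool on cell numbers with the log of retained cells as offset. Shares were also compared by two-sided exact permutation, whose smallest p is 0.1, or 0.25 for sign flips of 3 pairs. Shares of single samples carry Clopper-Pearson intervals of 95%, and a share of 0 is given the limit of 3 counts. These cover counting error only. The interaction of state and compartment was fitted with the sample as a block. DESeq2 1.42.0 was run beside edgeR on the expression sums, but not on the interaction.

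The 40 gene lists, the cell type markers, the tests and the other settings listed below were fixed before the data were examined. Lists with at least 5 tested genes (209 list and fit pairs) were tested with camera in limma 3.58.1 with the preset correlation of 0.01. With an estimated correlation 0 of the 60 calls held, and with fry 0 passed, so list results are given as values.

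Genes were named by a fixed rule. Genes past the threshold came first, of which there were none. Then up to 4 members per list past the list threshold were taken by lowest unadjusted p, together with the members at 1 CPM or more of the enteric neuron, pan-glial, Hirschsprung risk, neurotrophic ligand and posterior HOX lists, and the 5 genes with the lowest unadjusted p per direction in whole samples. Mitochondrial, sex-specific, variable-segment and some polymorphic genes are never named. This gave 310 genes, too many to print, so the text names the first 2 per list and the first 4 of the 5 lists by unadjusted p, 139 genes, with some others not reported here. These numbers were set after earlier, narrower selections, one of them picked by hand, had been tried on the alternatives and dropped.

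The pairing comes from the labels, which give each number to 1 patient. Deviations from the group means correlated within the pairs at 0.18, 0.72 and 0.75 in whole samples. In the class sums the correlations were above 0.1 except for patient 1 in fibroblasts (-0.078) and crypt cells (0.099). The fit with the patient as a block was run beside the fit without it. Further settings were DESeq2, its size factors, no filter on low counts, at least 500 genes per cell, at most 10% mitochondrial UMIs, doublets kept, other clustering resolutions (0.8 and 2.5), at least 50 cells, other denominators, other numbers of neuronal genes, cells thinned to 1000 UMIs, and each sample left out. Those chosen after seeing the data were no mitochondrial limit, at least 15 cells, shares of immune and stromal cells, and the block without patient 2 for expression and for abundance.

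The tests were tried on simulated counts with 200 changed genes per fit. In whole samples edgeR recovered 0% of changes of log2 1 and 0% of log2 3 with 0 false calls (16591 genes). Larger changes of log2 2 and 5 were added after that outcome, and edgeR recovered 2% and 78% with 5 false calls (16621 genes). In the 7 class fits it recovered 83% (NK, innate lymphoid or T cells, 3906 genes) to 97% (crypt cells, 11402 genes) of log2 3, but 4% to 24% of log2 1. The interaction test recovered 1% and 68% (13979 genes). A simulated list raised by log2 1 was called with the preset correlation in all fits but absorptive and B cells, where its adjusted p was 0.717 and 0.249, and 0 to 2 lists that were not raised were called per fit. With an estimated correlation, and with fry, the raised list was called in 3 of 8 fits and missed in the others (whole samples 0.288 and 0.302), so both also miss true changes of that size. Simulated genes were drawn independently, with no correlation between genes and no patient effect. The few false list calls therefore cannot be carried over to the real lists, where other splits of the samples gave 48 to 81 calls. Figures were drawn with matplotlib 3.10.9.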

Results

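Single-cell RNA sequencing was carried out on colon from 3 patients with Hirschsprung's disease, in which enteric ganglia are missing from the distal bowel. Each patient contributed a segment labelled healthy and a segment labelled aganglionic, so that the 6 libraries formed 3 within-patient pairs. The deposited UMI (unique molecular identifier) counts covered 41393 barcodes. Total UMIs were 25415926 in healthy 1, 61525452 in aganglionic 1, 44141273 in healthy 2, 61749717 in aganglionic 2, 38209954 in healthy 3 and 63881167 in aganglionic 3. The median mitochondrial share of a barcode was 8.53%, 25.02%, 22.2%, 32.3%, 6.44% and 7.76% in the same order, higher in the aganglionic library of each patient. After filtering, 4394, 3358, 3236, 3684, 4126 and 6811 cells were retained, with median UMIs per retained cell of 3245, 3371, 2935, 9259.5, 6018 and 6047. No 2 libraries agreed within sampling noise (chi-square per degree of freedom of 134 or more for every pair), so all 6 were counted separately.

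The first comparison asked which cell classes made up the healthy and the aganglionic segments. B cells, named like every class here from marker genes and so only B cell-like, made up 36.7% ± 18.7 (SD, n = 3) of healthy and 6.24% ± 4.34 of aganglionic cells. T cells made up 10.3% ± 6.17 and 2.06% ± 1.69. Germinal centre B cells, the proliferating B cells of lymphoid follicles, made up 2.89% ± 0.951 and 0.334% ± 0.293. Each of these 3 classes had a lower share in the aganglionic segment of 3 of 3 patients. B cells were 56.8% against 9.29% in patient 1, 19.8% against 1.28% in patient 2 and 33.3% against 8.15% in patient 3. Plasma cells, the antibody-secreting end stage of the B lineage, were at 0.928% ± 0.742 against 0.258% ± 0.190, also lower in 3 of 3 patients. A joint class of NK, innate lymphoid or T cells, counted apart from the T cells, was at 4.06% ± 3.35 and 3.51% ± 3.13. It was lower in 2 of 3 patients and higher in patient 1 (0.523% against 2.47%). All immune classes together held 58.4% ± 21.9 of healthy and 17.3% ± 12.04 of aganglionic cells, a difference of -41.1 percentage points (two-sided exact permutation p = 0.1, the smallest that 3 against 3 samples allow).

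With edgeR's quasi-likelihood test on cell numbers, 0 of 16 classes passed without a patient term, 2 (glia and germinal centre B cells) had an unadjusted p under 0.05, and no other count model was run. The log2 differences were -3.11 ± 1.398 (SE) for germinal centre B cells (adjusted p = 0.237), -2.55 ± 1.35 for B cells (adjusted p = 0.338) and -2.32 ± 1.34 for T cells (adjusted p = 0.354). With the patient as a block, edgeR called these 3 classes, at -3.35 (adjusted p = 0.0392), -2.85 (adjusted p = 0.0443) and -2.74 (adjusted p = 0.0443), each lower in 3 of 3 patients. Without patient 2, whose aganglionic library held 47 B cells, the blocked fit on the remaining 2 pairs called 0 classes, with the germinal centre B share at -2.59 (adjusted p = 0.120), the B cell share at -2.32 (adjusted p = 0.120) and the T cell share at -2.20 (adjusted p = 0.124). The mitochondrial share, higher in the aganglionic library of each patient, moved with these shares, and the limit of 25% removed cells unequally (78.8%, 49.97%, 54.2%, 42.8%, 80.4% and 85.7% of barcodes lay within it, in the order above).

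**Figure D1:**
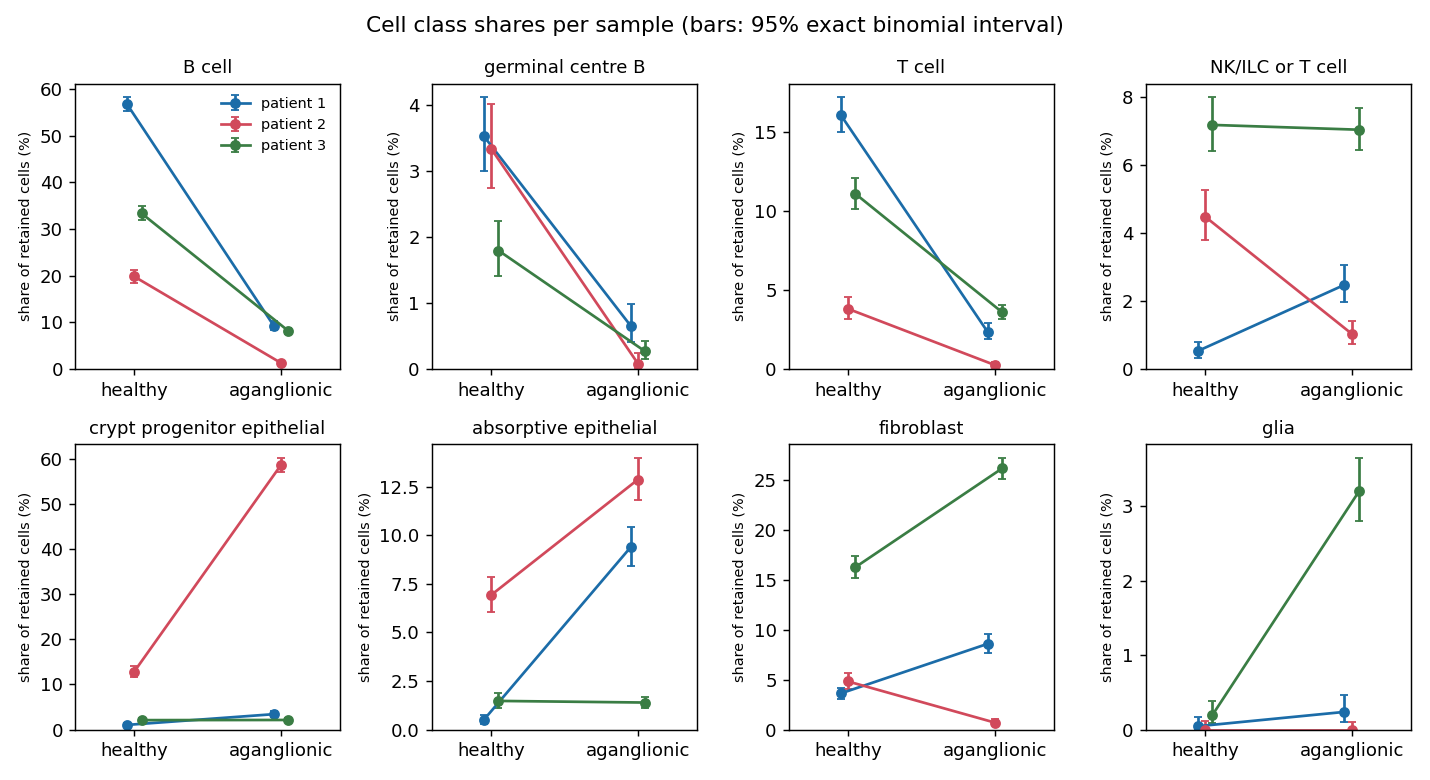
Share of retained cells (percent) per cell class in the 6 libraries, healthy and aganglionic. B cells fell between 19.8% and 56.8% of cells in the 3 healthy libraries and between 1.28% and 9.29% in the 3 aganglionic ones.

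Among the epithelial classes, crypt progenitor cells, which renew the colonic lining, held 5.33% ± 6.52 of healthy and 21.4% ± 32.2 of aganglionic cells (log2 difference 2.01 ± 1.33, edgeR adjusted p = 0.433, higher in 3 of 3 patients). The aganglionic mean rested on aganglionic 2, where they were 58.6% of cells. Without that library the log2 difference was -0.94, with its partner healthy 2 (12.8%) still in the healthy group. The healthy and aganglionic shares were 1.05% and 3.42% in patient 1, and 2.11% and 2.14% in patient 3. Absorptive cells were at 2.97% ± 3.46 against 7.88% ± 5.88 and goblet cells, the mucus secretors, at 3.44% ± 4.22 against 7.57% ± 6.95. Without aganglionic 2 the aganglionic means were 5.39% and 3.79%, and without healthy 2 the healthy means were 0.990% and 1.03%. In patient 3 both classes were slightly lower in the aganglionic library (1.48% against 1.39%, and 1.67% against 1.498%). Blood endothelial cells were at 5.09% ± 1.81 against 10.6% ± 8.58 and fibroblasts at 8.23% ± 6.97 against 11.8% ± 13.01, neither higher in every patient. Without aganglionic 3 these aganglionic means were 6.29% and 4.64%. Smooth muscle cells were at 3.22% ± 2.45 against 2.69% ± 1.85, macrophages and monocytes at 2.66% ± 0.762 against 4.09% ± 3.33, and mast cells at 0.922% ± 0.487 against 0.825% ± 0.590. The macrophage mean was 2.61% without aganglionic 1. Cells in clusters left without a name made up 12.4% ± 9.41 of healthy and 18.2% ± 15.4 of aganglionic cells, the latter 9.56% without aganglionic 1. One of them, cluster 5, led by POSTN and SOX6, was kept out of the smooth muscle class by a rule tightened after its genes were seen, and held 1.99% ± 1.09 and 4.80% ± 5.81, the latter 1.52% without aganglionic 3.

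**Figure D2:**
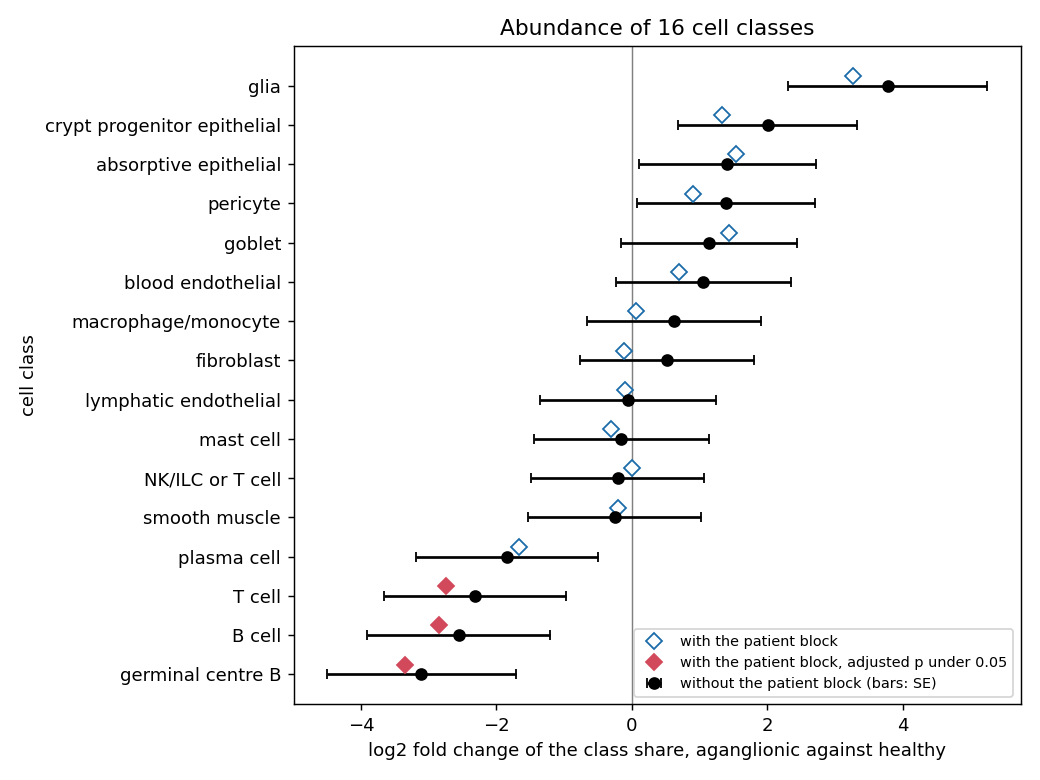
Log2 difference in abundance, aganglionic minus healthy, for each of the 16 cell classes with its standard error, from the fit without a patient term. Diamonds give the values with the patient as a block. Without the block germinal centre B cells lay lowest at -3.11 and glia highest at 3.78, and 0 of 16 classes passed. Filled diamonds mark the classes that passed with the block, which were germinal centre B cells, B cells and T cells.

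Glia, which ensheath enteric neurons and nerve fibres, came from a single cluster expressing S100B and SOX10. They numbered 2, 8, 0, 0, 8 and 218 cells in healthy 1, aganglionic 1, healthy 2, aganglionic 2, healthy 3 and aganglionic 3. Their shares were 0.0455% (95% Clopper-Pearson interval 0.00551 to 0.164) and 0.238% in patient 1, and 0.194% and 3.20% in patient 3. In patient 2, counts of 0 allowed shares of up to 0.0927% in the healthy and 0.0814% in the aganglionic library, for counting error only. The log2 difference of the glia share was 3.78 ± 1.47 (edgeR adjusted p = 0.199, lower in 0 of 3 patients) and 3.27 with the patient as a block (adjusted p = 0.0704). It was 4.36 (adjusted p = 0.0153) without aganglionic 2 but 0.52 (adjusted p = 0.878) without aganglionic 3, where the mean shares were 0.0798% and 0.119%. As a share of stromal cells, glia were 0.628% in healthy 3 and 5.70% in aganglionic 3.

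Aganglionosis is defined by missing enteric neurons, so cells with neuronal transcripts were counted next. Cells with a UMI in at least 3 of 8 neuronal genes, such as ELAVL4, STMN2 and SNAP25, numbered 2, 1, 0, 0, 6 and 4 in the order above. Their share differed by -0.034 percentage points between the groups (two-sided exact permutation p = 0.7), and was 0 in T cells of every library, which had median UMIs of 1876 to 5141. With 9 to 706 T cells per library, counts of 0 allowed shares of up to 0.425% to 33.3%. These limits lie above the highest marker cell share (0.145%, healthy 3), so T cells were too few to give a background. Of the cells with at least 3 neuronal genes, 6 lay in goblet cluster 16, which also held the 14 cells named enteroendocrine at resolution 2.5, and 1 in the glial cluster. STMN2, a microtubule regulator of neurites, was detected in 130, 104, 74, 22, 266 and 1079 cells, and it was also among the top 10 genes of fibroblast cluster 2. With at least 2 of the 8 genes the difference was 0.336, and without healthy 3 it was 0.0067, so no direction was resolved. Among 11 genes of the enteric neuron list that reached 1 CPM (counts scaled to a common total) in whole samples, 5 were higher and 6 lower. SYP, a synaptic vesicle protein, was at -0.46 ± 0.57, UCHL1 at -0.62 ± 1.07, ISL1 at 0.78 ± 1.397 and TAC1, the substance P precursor, at 0.76 ± 1.395 on the log2 scale. None of the 11 passed when adjusted over the list alone or over all genes.

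Expression was then compared in whole samples, where all retained cells of a library were summed. The genes with the lowest unadjusted p included RGS13, a regulator of G protein signalling in germinal centre B cells (ENSG00000127074, GRCh38 chromosome 1, 192636138 to 192660306), at 18.3 ± 2.05 CPM (SD, n = 3) in healthy and 2.35 ± 1.11 in aganglionic samples. GCG, the precursor of glucagon and GLP-1 in endocrine cells (ENSG00000115263, GRCh38 chromosome 2, 162142873 to 162152404), was at 0.258 ± 0.0504 and 5.25 ± 3.75 CPM. Their log2 differences were -2.95 ± 0.49 (SE) and 4.34 ± 0.76. Among genes lower in aganglionic samples, the other 4 of lowest p were BFSP2 (-3.76 ± 0.66), CAMP, an antimicrobial peptide precursor (-2.72 ± 0.48), STAG3 (-2.39 ± 0.45) and BCAS4 (-2.86 ± 0.54). Among genes higher there, the other 4 of lowest p were HSD17B2 (1.47 ± 0.30), the gel-forming mucin MUC5AC (3.47 ± 0.77), SERPINB5 (3.42 ± 0.77) and TNNC1 (2.15 ± 0.50). All 10 had the same direction in 3 of 3 patients and an edgeR adjusted p = 0.948. Of 16558 genes tested, edgeR called 0, with 773 at an unadjusted p under 0.05, while DESeq2 called 57, 10 higher and 47 lower. DESeq2 gave adjusted p = 9.6e-05 for RGS13, 2.7e-05 for GCG and 8.2e-06 for CAMP. On simulated counts with true changes of 3 log2 units, edgeR recovered 0% of the changed genes here and DESeq2 72% with 64 false calls.

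The gene lists of lymphocytes were lower in whole aganglionic samples, beside the lower B and T cell shares. All 9 tested immunoglobulin constant genes lay lower, with a median log2 difference of -1.95, IGLC2 at -4.02 ± 0.80 and IGHG3 at -5.08 ± 1.402. All 16 naive lymphocyte genes lay lower (median -1.58), with TCL1A, a coactivator of AKT in B cells, at -4.38 ± 1.02 and IGHD at -3.42 ± 1.08. Of 11 genes of class II antigen presentation, 10 lay lower (median -2.18), with CIITA, the class II transactivator, at -3.41 ± 1.08 and HLA-DOA at -2.76 ± 0.99. Camera gave adjusted p of 8.5e-12, 6.0e-10 and 4.8e-09 with the preset correlation for these 3 lists, and adjusted p = 0.802 for each with an estimated correlation. Tissue residency genes (1 higher, 12 lower, median -1.48) included CD69 at -2.75 ± 0.89 and ZNF683 at -2.05 ± 0.73. T cell cytotoxicity genes (1 higher, 18 lower, median -0.70) included IFNG at -2.85 ± 1.26 and CTSW at -1.12 ± 0.62, and regulatory T cell genes (2 higher, 12 lower, median -1.01) included IKZF2 at -1.72 ± 0.81 and CTLA4 at -2.20 ± 1.13. Their preset adjusted p was 0.000104, 0.000419 and 0.000946, and adjusted p = 0.821 for each with an estimated correlation. Adjusted over the list alone, 4 of the 9 immunoglobulin genes passed and none of the other 5 lists' genes did, against 0 over all genes tested.

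Interferon lists in whole samples had smaller medians. Type I interferon response genes (10 higher, 20 lower, median -0.27) included ISG20 at -1.17 ± 0.45 and EPSTI1 at -0.87 ± 0.49, with a preset adjusted p of 0.0369 and adjusted p = 0.901 with an estimated correlation. Without aganglionic 2 this list pointed the other way, with an adjusted p of 0.775. Genes induced by interferon gamma (5 higher, 13 lower, median -0.30) included PSMB9, an immunoproteasome subunit, at -0.64 ± 0.28, with a preset adjusted p of 0.0414 and adjusted p = 0.821 with an estimated correlation.

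Epithelial lists lay higher in whole aganglionic samples, beside the higher mean share of epithelial cells (11.7% ± 14.2 against 36.8% ± 43.6). For these named classes the mean rested on aganglionic 2 (86.6%), since without it the aganglionic mean was 11.96%. Its partner healthy 2 was at 28.0%, and without healthy 2 the healthy mean was 3.60%. The healthy and aganglionic shares were 1.93% and 18.9% in patient 1, and 5.26% and 5.04% in patient 3. Unnamed clusters with epithelial genes are not in that share. Of these, cluster 24 (with DUOX2, DUOXA2 and MUC12 among its top genes) held 298 of its 318 cells and cluster 32 (with PI3 and TFF1) 165 of 167 in aganglionic 1, and cluster 14 (PRAC1, LGALS4) held 25, 98, 411, 104, 37 and 19 cells in the order above. Cluster 7, left unnamed for want of detected markers, held 201, 451, 275, 84, 19 and 24 cells. At resolution 0.8 an absorptive cluster held 215, 685, 279, 95, 23 and 25 cells. It shared HIST2H4B and PCK1 with cluster 7 among its top genes. The epithelial share of aganglionic 1 may therefore lie well above 18.9%, and the difference need not rest on aganglionic 2 alone. Genes of the distal colon epithelium (11 higher, 2 lower, median 1.505) included CA1, a carbonic anhydrase, at 1.78 ± 0.49 and INSL5, a hormone of distal endocrine cells, at 4.65 ± 1.32. Epithelial stress and antimicrobial genes were 15 of 15 higher (median 1.29), with DUOXA2, the maturation factor of the oxidase DUOX2, at 4.82 ± 1.90 and the protease inhibitor PI3 at 2.55 ± 1.08. Mucus and goblet genes (18 higher, 1 lower, median 0.85) included TFF1 at 2.93 ± 1.14 and MUC12 at 1.88 ± 0.82, and colonocyte transport genes (20 higher, 1 lower, median 0.74) included the water channel AQP8 at 3.19 ± 1.72. With the preset correlation adjusted p was 1.5e-06, 1.2e-05, 8.5e-06 and 0.000223 for these 4 lists, and an estimated correlation gave adjusted p = 0.802 for the first 2 and 0.821 for the others. Respiratory chain genes were 27 of 27 higher (median 0.57), with NDUFC1 at 0.76 ± 0.45 and NDUFB4 at 0.64 ± 0.40, and basement membrane genes 21 of 21 (median 0.78), with LAMB3 at 1.43 ± 0.69 and AGRN at 0.73 ± 0.37. Their preset adjusted p was 2.5e-05 and 0.00601, and adjusted p = 0.821 for each with an estimated correlation. None of the genes of these 6 lists passed when adjusted over the list alone.

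**Figure D3:**
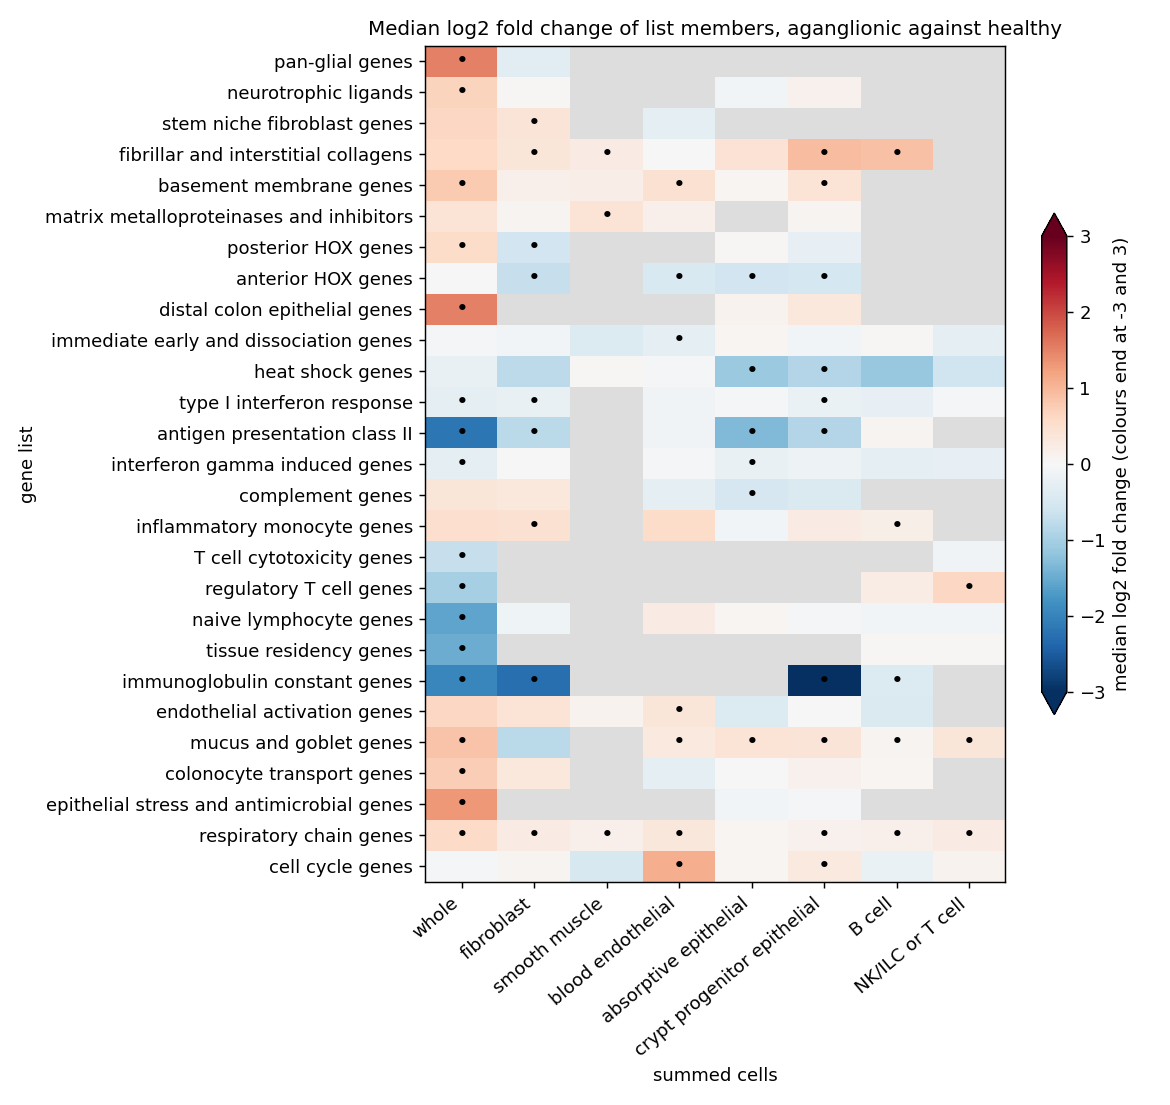
Median log2 difference, aganglionic minus healthy, of each gene list (27 lists) in each fit (8 fits, whole samples and 7 cell classes). The 60 dots mark lists past the threshold with the preset correlation, of which 0 passed with an estimated correlation, and colours end at -3 and 3.

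Genes tied to Hirschsprung's disease and to the innervation of the gut were reported whatever their test. Of 20 Hirschsprung risk genes that reached 1 CPM, 13 were higher and 7 lower (median 0.51), with the receptor kinase ERBB2 at 0.91 ± 0.57, the endothelin-converting enzyme ECE1 at 0.52 ± 0.34 and the guidance ligand SEMA3C at 0.74 ± 0.52. TTF1, at -0.59 ± 0.39, is counted among the 20 but encodes a termination factor of RNA polymerase I, and entered that list only through an alias it shares with another gene. Of 20 neurotrophic ligands, 16 were higher and 4 lower (median 0.70), with the cytokine LIF at 1.49 ± 0.51, BMP2 at 1.11 ± 0.47 and SEMA3F at 1.33 ± 0.68. Of 18 pan-glial genes at 1 CPM or more, 17 were higher (median 1.4999), with NRXN3 at 2.13 ± 1.05, XKR4 at 3.44 ± 2.10 and FOXD3 at 2.33 ± 1.61. XKR4 and FOXD3 were at -1.17 and -1.12 without aganglionic 3, the library with 218 glia. Of 14 posterior HOX genes, which mark position along the body axis, 13 were higher (median 0.55), with HOXB13 at 1.69 ± 0.79, HOXD11 at 2.32 ± 1.14, HOXD9 at 1.09 ± 0.58 and HOXD13 at 2.66 ± 1.58. Camera's adjusted p with the preset correlation was 0.183 for the risk genes, 0.0176 for the ligands, 0.0426 for the pan-glial and 0.00623 for the posterior HOX list. With an estimated correlation the last 3 had adjusted p = 0.821, 0.901 and 0.821. With the patient block the preset adjusted p of the ligands and of the pan-glial list was 0.0628 each, and the pan-glial list pointed the other way without aganglionic 3. None of these genes passed when adjusted over the list alone, and 1 of them, LIF, had an unadjusted p under 0.05.

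Within crypt progenitor cells, 3 genes passed with the patient as a block, all higher in the aganglionic segment of 3 of 3 patients and named here, outside the rule for named genes, after their values were seen. CHGA, a granin of endocrine granules (ENSG00000100604, GRCh38 chromosome 14, 92923080 to 92935293), was at 0.260 ± 0.226 CPM (SD, n = 3) in healthy and 220 ± 173 in aganglionic sums. TPH1, the enzyme that commits tryptophan to serotonin in enterochromaffin cells (ENSG00000129167, GRCh38 chromosome 11, 18017564 to 18042426), was at 0.157 ± 0.191 and 23.5 ± 20.9 CPM. CHGB (ENSG00000089199, GRCh38 chromosome 20, 5911430 to 5925361) was at 0.534 ± 0.374 and 25.2 ± 24.5 CPM. Blocked log2 differences were 8.06 ± 0.63, 6.31 ± 0.52 and 5.52 ± 0.40 (SE, edgeR adjusted p = 0.0203 each), and the unblocked ones 9.20, 7.15 and 6.23 with adjusted p of 0.399, 0.808 and 0.890. Most of the CHGA counts came from few cells: 1, 4 and 2 crypt cells of aganglionic 1, 2 and 3 with at least 10 CHGA UMIs held 1006 of 1010, 473 of 497 and 2387 of 2397, and healthy crypt sums held no such cell. No endocrine class was resolved at the resolution used, while at resolution 2.5 a cluster led by CHGA and TPH1 held 0, 2, 1, 1, 6 and 4 cells in the order above, 7 healthy and 7 aganglionic, all of them in goblet cluster 16 and none in the crypt sums. The CHGA difference in crypt sums thus rested on 7 cells. Without the block edgeR called 0 of 11269 genes, with 222 at an unadjusted p under 0.05, and DESeq2 called 16, 6 higher and 10 lower. Without patient 2 the blocked fit called only CHGA.

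Among the lists within crypt cells, immunoglobulin transcripts were 5 of 5 lower (median -6.90), with IGHA1 at -6.90 ± 1.22 and JCHAIN at -7.69 ± 1.42, beside the lower plasma and B cell shares of the same libraries. All 5 passed when adjusted over the list alone and 0 over all genes, and camera gave an adjusted p of 4.5e-22 with the preset correlation and adjusted p = 0.751 with an estimated correlation. JCHAIN and IGHA1 together had 24 of 1473363 UMIs in healthy 1 and 24 of 3464870 in aganglionic 1. They had 3430 of 9088652 and 56 of 24876572 in patient 2, and 2111 of 2608943 and 10 of 6622423 in patient 3. The size of the difference thus rested on patients 2 and 3. It exceeded the log2 differences of the plasma (-1.84) and B cell (-2.55) shares. Class II genes were 9 of 9 lower (median -0.89), with IFI30 at -1.77 ± 0.57 and CD74, the class II invariant chain, at -1.37 ± 0.61. Mucus and goblet genes (15 higher, 2 lower, median 0.38) included TFF1 at 1.71 ± 0.49 and MUC13 at 0.62 ± 0.25, and basement membrane genes (11 higher, 3 lower, median 0.41) included LAMB3 at 0.55 ± 0.23. Anterior HOX genes (1 higher, 8 lower, median -0.53) included HOXA6 at -1.28 ± 0.52 and HOXA3 at -1.17 ± 0.49. Preset adjusted p was 1.6e-06, 0.000161, 0.00446 and 0.00025 for these 4 lists, and adjusted p = 0.802 for each with an estimated correlation. Cell cycle genes (20 higher, 2 lower, median 0.30) included PCNA at 0.57 ± 0.31 and TYMS at 0.64 ± 0.43, type I interferon genes (6 higher, 14 lower, median -0.20) included EPSTI1 at -0.91 ± 0.40 and IFITM1 at -0.56 ± 0.25, and respiratory chain genes were 27 of 27 higher (median 0.13), with NDUFB2 at 0.24 ± 0.21 and UQCRH at 0.22 ± 0.21. Collagen and matrix genes (11 higher, 3 lower, median 0.93) included TIMP1 at 1.01 ± 0.37 and COL6A1 at 1.27 ± 0.58. With the preset correlation adjusted p was 0.00025, 0.00729, 0.0267 and 0.0295, and adjusted p = 0.821 for each with an estimated correlation. The cell cycle list pointed the other way without healthy 1, and the collagen list without healthy 2 or aganglionic 3. The source of the collagen counts in crypt sums was not tested. Crypt cells joined cluster 0 (on average 81.2% of healthy and 66.6% of aganglionic crypt cells) and cluster 17, with CENPW, CDC20 and CCNB1 among its top genes. Cluster 17 held 0 of 46, 39 of 115, 110 of 415, 248 of 2158, 26 of 87 and 80 of 146 crypt cells in the order above. Its share was higher in the aganglionic library of patients 1 and 3 and lower in that of patient 2. How far this make-up accounts for the cell cycle values was not tested.

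In absorptive epithelial cells, HLA-DRA, the class II alpha chain, was at 32.4 ± 19.0 CPM (SD, n = 3) in healthy and 6.14 ± 5.00 in aganglionic sums (log2 difference -2.22 ± 0.65) and CD74 at -1.39 ± 0.46, each lower in 3 of 3 patients with an edgeR adjusted p of 0.9998. Of 8 class II genes 6 lay lower (median -1.33), and 1 passed when adjusted over the list alone. Complement genes (1 higher, 5 lower, median -0.51) included C2 at -0.94 ± 0.35 and CFB at -1.10 ± 0.51, anterior HOX genes (2 higher, 5 lower, median -0.57) included HOXA3 at -1.31 ± 0.60 and HOXA6 at -1.18 ± 0.63, and genes induced by interferon gamma (2 higher, 9 lower, median -0.21) included the guanylate-binding proteins GBP2 at -0.59 ± 0.27 and GBP1 at -1.04 ± 0.51. Mucus and goblet genes (13 higher, 3 lower, median 0.41) included TFF1 at 1.41 ± 0.44 and ITLN1, an intelectin, at 0.70 ± 0.33. Camera's adjusted p with the preset correlation was 2.5e-07 for class II, 0.000946 for complement, 0.00292 for HOX, 0.00452 for interferon gamma and 3.6e-05 for mucus genes, and adjusted p = 0.802 for each with an estimated correlation. Of 10482 genes edgeR called 0, with 132 at an unadjusted p under 0.05, and DESeq2 called 1. Healthy 1 held 22 of these cells, and clusters 25 (patient 1) and 10 (the others) held most of the class. At resolution 0.8 a single absorptive cluster held 215 cells of healthy 1.

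Heat shock genes, the protein-folding chaperones, were 15 of 15 lower in absorptive sums (median -1.10) with DNAJA1 at -0.99 ± 0.53 and HSPD1 at -1.10 ± 0.62, and 15 of 16 lower in crypt sums (median -0.87) with DNAJB4 at -1.91 ± 1.07 and HSPA1B at -1.87 ± 1.17. Preset adjusted p was 0.000226 and 0.0276, and adjusted p = 0.821 and 0.901 with an estimated correlation. Both directions rested on healthy 1, since without it the lists lay higher, with preset adjusted p = 2.83e-05 for heat shock genes in absorptive epithelial and 3.01e-07 for heat shock genes in crypt progenitor epithelial sums.

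In fibroblasts, collagen and matrix genes were 26 of 29 higher in the aganglionic sums (median 0.37). COL6A3, a microfibrillar collagen chain, was at 448 ± 130 CPM (SD, n = 3) in healthy and 804 ± 156 in aganglionic sums (log2 difference 0.85 ± 0.33, higher in 3 of 3 patients) and THBS2, a matricellular protein, at 0.98 ± 0.46. PI16, a marker of adventitial fibroblasts, was at 83.0 ± 51.1 and 278 ± 120 CPM (1.65 ± 0.51), and SFRP1, a WNT antagonist of the same stem niche list (10 higher, 4 lower, median 0.39), at 0.74 ± 0.37. Anterior HOX genes were 6 of 6 lower (median -0.69), with HOXA3 at -1.497 ± 0.46 and HOXA6 at -1.33 ± 0.56, and posterior HOX genes 5 of 6 lower (median -0.58), with HOXA11 at -0.93 ± 0.38 and HOXA9 at -1.20 ± 0.48, while the posterior list had a positive median in whole samples. With the preset correlation adjusted p was 7.8e-07 for collagens, 0.0216 for the niche, 0.00133 for anterior and 0.0341 for posterior HOX genes, and with an estimated correlation adjusted p = 0.821, 0.802, 0.802 and 0.821. All of these genes had an edgeR adjusted p of 1 over all genes.

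Lists of immune-linked and respiratory chain genes were also called in fibroblast sums, with the preset correlation only. Immunoglobulin genes (2 higher, 3 lower, median -2.27) included IGHM at -2.75 ± 0.56 and IGLC2 at -3.51 ± 0.83, both past the threshold when adjusted over the list alone, beside the lower B cell share. JCHAIN and IGHA1 together went the other way in patient 3, with 230 of 5013665 UMIs in healthy 3 and 2733 of 13490001 in aganglionic 3. They were lower in patient 1 (33 of 981819 and 22 of 2091654) and patient 2 (63 of 693379 and 1 of 56790). Class II genes (1 higher, 6 lower, median -0.80) included CD74 at -1.63 ± 0.55 and HLA-DPB1 at -0.80 ± 0.41, and type I interferon genes (3 higher, 25 lower, median -0.22) included EPSTI1 at -0.63 ± 0.30 and XAF1 at -0.68 ± 0.40. Respiratory chain genes (26 higher, 1 lower, median 0.24) included COX6C at 0.65 ± 0.31 and COX8A at 0.37 ± 0.29. The inflammatory monocyte list (6 higher, 1 lower, median 0.45) included the chemokine CXCL8 at 2.67 ± 1.15, which was at -1.62 without aganglionic 1, and PTGS2 at 0.77 ± 0.44. Camera's adjusted p with the preset correlation was 0.000161, 0.0181, 0.0045, 0.00025 and 0.0295 in this order, and with an estimated correlation adjusted p = 0.802, 0.821, 0.821, 0.821 and 0.802. Of 9660 genes edgeR called 0, with 151 at an unadjusted p under 0.05, and DESeq2 called 0. Fibroblasts also lay in different clusters, with 71.0% of healthy and 52.6% of aganglionic fibroblasts on average in cluster 2. Cluster 33 held 115 of 288 fibroblasts in aganglionic 1 and 0 of 159 in healthy 1, and cluster 35, with PI16 among its top genes, held 130 cells in aganglionic 3 and 2 in healthy 3. Aganglionic 2 held 26 fibroblasts, and the deviations of the patient 1 pair correlated at -0.078.

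In blood endothelial cells, 10 of 10 cell cycle genes lay above the healthy level (median log2 difference 1.10). CDK1, the mitotic kinase, was at 4.24 ± 0.127 CPM (SD, n = 3) in healthy and 20.5 ± 12.1 in aganglionic sums (log2 difference 1.89 ± 0.49, higher in 3 of 3 patients) and PCNA, the replication clamp, at 26.0 ± 7.20 and 66.1 ± 41.5 (1.499 ± 0.40, 2 of 3), each with an edgeR adjusted p of 0.9993. The healthy sums held 767022, 683406 and 1575532 UMIs and that of aganglionic 2 held 182182. Few UMIs thus lay behind the healthy CDK1 values and their small SD. Endothelial activation genes (14 higher, 2 lower, median 0.35) included ESM1, an endothelial proteoglycan, at 2.12 ± 0.70 and PGF at 0.94 ± 0.49. Respiratory chain genes (25 higher, 2 lower, median 0.33) included NDUFA4 at 0.67 ± 0.26 and COX8A at 0.45 ± 0.23, and basement membrane genes (11 higher, 3 lower, median 0.47) included COL18A1 at 0.79 ± 0.30 but LAMA3 at -1.03 ± 0.37. Immediate early genes (5 higher, 20 lower, median -0.30) included NR4A1 at -1.54 ± 0.58 and KLF2 at -0.61 ± 0.27, and anterior HOX genes (1 higher, 6 lower, median -0.45) included HOXA6 at -1.59 ± 0.53 and HOXA5 at -0.58 ± 0.33. Preset adjusted p was 8.6e-07, 0.0192, 1.9e-05, 0.0424, 0.0181 and 0.0345 in this order, and adjusted p = 0.802 for cell cycle genes and 0.821 for the others with an estimated correlation. The activation list pointed the other way without aganglionic 1, the basement membrane list without aganglionic 3 and the immediate early list without healthy 1.

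Adjusted over the list alone, 3 of 10 endothelial cell cycle genes passed, against 0 over all genes. Of 9132 genes edgeR called 0, with 374 at an unadjusted p under 0.05, and DESeq2 called 0. The blocked fit also called 0, but 671 (359 higher, 312 lower) without patient 2. Mucus and goblet genes were also counted in the endothelial sums (8 higher, 2 lower, median 0.28), with SPINK4 at 1.398 ± 1.35 and CLCA1 at -1.42 ± 1.44. Their source there was not tested. The mean goblet share was 3.44% in healthy and 7.57% in aganglionic samples, the latter 3.79% without aganglionic 2. The mucus and goblet list had a preset adjusted p of 0.0216 and adjusted p = 0.821 with an estimated correlation.

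In B cells, the patient block gave 61 calls among 8623 genes, 46 higher and 15 lower in the aganglionic segment. The class-switched heavy chains IGHA1 and IGHG1 were lower, at -1.93 ± 0.41 (edgeR adjusted p = 0.00441) and -2.09 ± 0.48 (adjusted p = 0.00868), in 2 of 3 and 3 of 3 patients, and the chemokine CCL3 was higher, at 1.68 ± 0.36 (adjusted p = 0.00447, 3 of 3). Among the 46 higher genes, 17 were over 4-fold more abundant in crypt epithelial sums, among them KRT8, KRT18 and EPCAM (picked after their values were seen), against 0 of the 15 lower genes and 592 of 8615 genes compared, so epithelial transcripts moved with this comparison. Without the block edgeR called 0 genes, with 198 at an unadjusted p under 0.05, and DESeq2 called 0. Without patient 2 the blocked fit called 69, of which 50 were among the 61. Clusters 1 in healthy 1, 4 in aganglionic 1 and patient 2, and 3 in patient 3 held most of the class.

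Among the B cell lists, immunoglobulin constant genes (2 higher, 6 lower, median -0.41) were led by IGHA1 at -2.56 ± 0.67 and IGHG1 at -2.85 ± 1.12 without the block, and 1 passed when adjusted over the list alone. Collagen and matrix genes (6 of 6 higher, median 0.89) included SPARC at 1.80 ± 0.56 and COL1A2 at 1.66 ± 0.62, respiratory chain genes (24 higher, 3 lower, median 0.16) included NDUFB4 at 0.44 ± 0.32 and UQCRH at 0.40 ± 0.33, and inflammatory monocyte genes (4 higher, 2 lower, median 0.16) included CXCL8 at 1.66 ± 0.51. Mucus and goblet genes (8 higher, 5 lower) had a median of 0.08 and a mean of -0.25, with CLCA1 at -2.81 ± 1.53 and TFF3 at -1.21 ± 1.29. With the preset correlation adjusted p was 0.0181, 0.00108, 0.0167, 0.0341 and 0.0335 in this order. With an estimated correlation adjusted p = 0.802, 0.802, 0.821, 0.802 and 0.901. Collagen and mucus genes are foreign to B cells, and the source of their counts in these sums was not tested. The mean stromal share was 17.5% in healthy and 27.7% in aganglionic samples, the latter 13.4% without aganglionic 3.

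In the class of NK, innate lymphoid or T cells, regulatory T cell genes were 5 of 5 higher (median 0.63), with ENTPD1, the ectonucleotidase CD39, at 57.8 ± 30.1 CPM (SD, n = 3) in healthy and 153 ± 99.8 in aganglionic sums (log2 difference 1.00 ± 0.48) and the inhibitory receptor TIGIT at 0.63 ± 0.31, each higher in 3 of 3 patients. Respiratory chain genes (23 higher, 3 lower, median 0.24) included UQCR11 at 0.43 ± 0.29 and NDUFS5 at 0.38 ± 0.31, and mucus genes (5 higher, 1 lower, median 0.37), foreign to this class, included SPINK4 at 1.13 ± 1.45 and MUC2 at 1.03 ± 1.36. Camera's adjusted p with the preset correlation was 8.5e-06, 0.0039 and 0.0176, and adjusted p = 0.751, 0.821 and 0.821 with an estimated correlation. Of 3990 genes edgeR called 0, with 29 at an unadjusted p under 0.05, and DESeq2 called 0. Healthy 1 held 23 of these cells.

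In smooth muscle, the contractile layer of vessels and bowel wall, the matrix protease ADAMTS4 was at 146 ± 62.1 CPM (SD, n = 3) in healthy and 404 ± 87.7 in aganglionic sums (log2 difference 1.43 ± 0.36, higher in 3 of 3 patients, edgeR adjusted p of 0.9996). Metalloproteinases and inhibitors (5 higher, 1 lower, median 0.41) also included ADAMTS9 at 0.52 ± 0.32, and 1 of 6 passed when adjusted over the list alone. Collagen and matrix genes (16 higher, 1 lower, median 0.24) included COL12A1 at 0.93 ± 0.45 and THBS1 at 0.55 ± 0.29, and respiratory chain genes (23 higher, 4 lower, median 0.15) included COX5A at 0.48 ± 0.31 and NDUFC1 at 0.35 ± 0.25. Preset adjusted p was 0.00623, 0.0181 and 0.0369, and with an estimated correlation adjusted p = 0.802, 0.821 and 0.802. Of 4053 genes edgeR called 0, with 94 at an unadjusted p under 0.05, and DESeq2 called 0. With the patient block the count was 0, and 61 (34 higher, 27 lower) without patient 2. The collagen list pointed the other way without aganglionic 3.

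The last comparison asked whether stromal and immune cells differed between the segments by different amounts. The interaction of state and compartment was tested on 14093 genes, of which edgeR called 0, with 1159 at an unadjusted p under 0.05, and no other tool was run. The 3 genes with the lowest p, chosen after their values were seen, were TMEM176B (-2.42 ± 0.36), DMXL2 (-2.81 ± 0.46) and GAS2L1 (-2.89 ± 0.47), with an adjusted p of 0.0889 each. TMEM176B was at -0.66 in stromal and 1.86 in immune sums. The make-up of the immune sums moved with the state, with macrophages and monocytes at 4.99% ± 1.96 (SD, n = 3) of healthy and 21.1% ± 8.46 of aganglionic immune cells and B cells at 60.7% ± 8.83 and 36.3% ± 3.97. Without healthy 3 the count was 116 and without healthy 2 it was 19.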

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

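Results under at least 15 cells, shares of immune and stromal cells, no mitochondrial limit with doublets kept, and the block without patient 2 come from tests chosen after the data were seen. Of 139 named genes under all settings, 1824 comparisons kept direction and side of the threshold, 49 newly passed and 23 turned direction, and over all 310 genes of the rule these counts were 4028, 65 and 149. The cause was not tested for any change below, except that leaving out a sample or a filter changes which samples or genes enter. Few cells limit the depth of the class fits, from 22 absorptive cells in 1 library upward.

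The replicate block, which uses the pairing by patient, gave 61 calls for B cell expression, 3 for crypt progenitor epithelial expression, 64 for expression within cell classes and 3 for cell class abundance, where the fit without it gave 0 each. For gene lists it gave 0 calls with an estimated correlation, as an estimated correlation without the block (0) and fry (0) did, against 60 with the preset one, or 64 with the preset one and the block. Preset calls of gene lists were 59 with DESeq2 size factors, 63 with doublets kept and 61 to 71 when a sample was left out. Of the 60 lists, 54 stayed called and 6 lost the call with the block, and when a sample was left out 38 to 47 stayed called in their direction, 11 to 19 lost the call and up to 4 turned. The block turned ISL1 in whole samples (-0.091), TFF3 in B cell (0.35) and CLCA1 in blood endothelial sums (0.31), the NK/ILC or T cell share (0.0074) and the fibroblast share (-0.12). The block changed no other count of calls among genes or shares. Without patient 2 the blocked fit gave 69 calls for B cell expression, 671 for blood endothelial expression, 61 for smooth muscle expression, 1 for crypt progenitor epithelial expression and 802 for expression within cell classes. That fit turned CLCA1 in B cell (0.045) and TFF3 in B cell sums (1.10), the NK/ILC or T cell share (1.06), the lymphatic endothelial share (0.35) and the mast cell share (0.47).

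DESeq2 called 57 genes in whole-sample expression, 1 in absorptive epithelial expression, 16 in crypt progenitor epithelial expression and 17 in expression within cell classes. Without the filter on low counts edgeR called 52 genes in absorptive epithelial, 26 in B cell, 87 in blood endothelial, 17 in crypt progenitor epithelial, 23 in fibroblast, 7 in NK/ILC or T cell and 22 in smooth muscle expression, 234 in expression within cell classes and 362 for the compartment interaction. At most 10% mitochondrial UMIs gave 12 calls in absorptive epithelial expression, 1 in crypt progenitor epithelial expression and 13 in expression within cell classes, and turned DNAJA1 in absorptive epithelial (0.17) and HSPD1 in absorptive epithelial sums (0.22) and the lymphatic endothelial share (0.33). At least 15 cells gave 1 call in expression within cell classes, from goblet cells. At resolution 2.5 the smooth muscle share was at 0.076.

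As shares of non-epithelial cells, cell class abundance gave 3 calls, and the NK/ILC or T cell share (0.34), lymphatic endothelial share (0.53), mast cell share (0.36) and smooth muscle share (0.70) turned. As shares of immune and stromal cells, cell class abundance gave 1 call, and the NK/ILC or T cell share (0.61), lymphatic endothelial share (0.94), mast cell share (0.66) and smooth muscle share (1.11) turned. Within compartments, the NK/ILC or T cell share (1.43), crypt progenitor epithelial share (-0.12), fibroblast share (-0.37), goblet share (-0.049) and mast cell share (1.49) turned. With at least 2 genes the neuron marker cells differed by 0.336 points, and leave-one-out values ran from -0.066 to 0.0067 (without healthy 3). A neuronal difference of exactly 0 after thinning was not counted as a turn, a choice made after it was seen.

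Leaving out each sample gave 0 to 2 calls in crypt progenitor epithelial expression, 0 to 1 in fibroblast expression, 0 to 2 in expression within cell classes, 0 to 1 in cell class abundance and 0 to 116 for the compartment interaction. Genes whose direction turned without healthy 1 ranged from -0.91 to 0.12 (SYP in whole samples), -1.34 to 0.071 (DNAJA1 in absorptive epithelial), -1.54 to 0.20 (HSPD1 in absorptive epithelial), -2.46 to 0.71 (DNAJB4 in crypt progenitor epithelial) and -2.51 to 1.20 (HSPA1B in crypt progenitor epithelial). Without healthy 2 the turned ranges were -4.02 to 0.69 (CLCA1 in B cell), -2.04 to 2.10 (TFF3 in B cell) and -3.43 to 4.12 (CLCA1 in blood endothelial). Without aganglionic 1 they were -2.14 to 4.24 (SPINK4 in blood endothelial), -1.62 to 3.26 (CXCL8 in fibroblast), -0.12 to 4.25 (MUC2 in NK/ILC or T cell) and, also without healthy 3, -0.50 to 5.45 (SPINK4 in NK/ILC or T cell). Without aganglionic 3 they were -1.67 to 1.49 (ISL1 in whole samples), -1.17 to 4.23 (XKR4 in whole samples) and -1.12 to 3.24 (FOXD3 in whole samples).

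Among shares, the leave-one-out range was -1.21 to 0.49 for the NK/ILC or T cell share, -0.38 to 0.73 for the lymphatic endothelial share, -0.77 to 0.30 for the mast cell share and -0.98 to 0.57 for the smooth muscle share, turned without aganglionic 2 or healthy 3. The crypt progenitor epithelial share ranged from -0.94 (without aganglionic 2) to 3.76, the macrophage/monocyte share from -0.026 (without aganglionic 1) to 1.15 and the fibroblast share from -0.83 (without aganglionic 3) to 1.48.

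Gene lists that turned had these ranges of adjusted p with the preset correlation. Without healthy 1 the range was 2.23e-13 to 0.159 for heat shock genes in absorptive epithelial, 2.34e-08 to 0.830 for heat shock genes in crypt progenitor epithelial, 7.24e-11 to 0.424 for cell cycle genes in crypt progenitor epithelial and 0.000751 to 0.962 for immediate early and dissociation genes in blood endothelial sums. For endothelial activation genes in blood endothelial sums (without aganglionic 1) it was 6.68e-07 to 0.561, and for the type I interferon response in whole samples (without aganglionic 2) 1.56e-06 to 0.775. Without aganglionic 3 it was 8.32e-10 to 0.657 for pan-glial genes in whole samples, 6.92e-05 to 0.979 for basement membrane genes in blood endothelial, 9.19e-05 to 0.557 for fibrillar and interstitial collagens in smooth muscle and, also without healthy 2, 8.29e-09 to 0.980 for fibrillar and interstitial collagens in crypt progenitor epithelial sums.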

Other observations

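The tests of glia as a share of stromal cells, of lymphocytes as shares of immune and stromal cells, of immunoglobulin ratios by patient and of the block without patient 2 were chosen after the data were seen, as were the clusters named in the next paragraph.

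Some clusters came mostly from 1 or 2 aganglionic libraries. Clusters 32, 24 and 38 were in no class, while clusters 33 and 35 were part of the fibroblast sums. Cluster 32, epithelial cells led by REG1A, PI3 and SLC6A14 with a median of 49541 UMIs, held 165 of its 167 cells in aganglionic 1, and cluster 24, led by DUOX2, MUC5B and MUC12, held 298 of 318 there. Cluster 33, fibroblasts led by PLA2G2A, TNFAIP6 and C3, held 115 of 144 cells in aganglionic 1. Cluster 35, fibroblasts led by APOD, ANGPTL7 and PI16, held 130 of 134 in aganglionic 3. Cluster 38, led by the matrix metalloproteinase genes MMP3, MMP1 and MMP10, was at 0.061% ± 0.0606 (SD, n = 3) of healthy and 0.536% ± 0.443 of aganglionic cells (two-sided exact permutation p = 0.3), with 25 cells in aganglionic 1 and 57 in aganglionic 3. A cluster held by 1 library cannot be separated from that patient or sample.

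The lower B, germinal centre B and T cell shares were set against technical explanations. More epithelial cells in the denominator would move all 3 toward 0, but without the named epithelial classes the value nearest 0 was -1.95, beside -2.32 over all cells. That denominator still held unnamed clusters with epithelial genes. As shares of immune and stromal cells alone the value nearest 0 was -1.57 ± 0.79 (SE), which is not below -1 by more than its error, so a part played by those clusters stays open. Unequal removal by the mitochondrial limit was predicted to leave B and T cell markers level without it. Their median without that limit was -2.68 (beside -2.70 with it), 20 of 20 markers lower. Lifting the limit thus did not bring the marker counts back. These were UMI sums over whole libraries, still limited to at least 300 genes, in which removed lymphocytes with few UMIs would hardly show. The test therefore does not settle unequal removal of cells. Also open is the position of the segments along the colon and the depth of wall sampled, which go with the state here, and a biological difference between the segments was not tested apart from them. The lower shares may therefore reflect where the tissue lay as well as its innervation.

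Lower immunoglobulin and class II transcripts outside B cells could come from free RNA of B and plasma cells, which were fewer in aganglionic samples. A single source of free RNA would hold the log2 ratio of IGKC to JCHAIN and IGHA1 constant within a sample, and its median absolute deviation was 0.583 over 24 classes and samples, between the bounds set for it. In patients 1 and 2 it was 0.284 over healthy 1, aganglionic 1 and healthy 2, as aganglionic 2 had too few counts. That is within the bound for 1 pool, but IGKC itself was at 338 CPM in crypt and 58.2 in absorptive sums of healthy 2, so the source is left open. In patient 3 it was 1.80, with 8 of 10 values above 1, but a few low ratios pulled down the sample means behind these values. The ratio was -4.89 in fibroblast sums of aganglionic 3, and -2.003 in fibroblast and -1.15 in crypt sums of healthy 3. In the other sums of patient 3 it lay between 0.60 and 2.52. This argues against 1 pool as the only source in those fibroblast and crypt sums, and does not settle it for the other classes. Plasma cells or doublets within the epithelial and stromal sums, or the cells' own transcripts, were not tested and stay open. Absorptive cells held over 4 times the class II counts per B cell count of B cells in 0 of 6 samples (median fold 1.58), so free RNA and the cells' own transcription cannot be told apart for class II.

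The glia of aganglionic 3 were set against more of all stromal cells in that library. The lower bound of the glial share of stromal cells there was 4.04 times the upper bound in healthy 3 (9.07 times for the shares themselves), which argues against it. Sampling of a nerve trunk, or a deeper piece of the wall, may be the source and was not tested.

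The 6 samples make 10 splits of 3 against 3, too few for a share under 0.05. For whole samples the real split gave 0 calls and the highest other 2592, from healthy 1, healthy 3 and aganglionic 3 against the rest, and 10 of 10 splits gave at least the real count, as for every result with 0 calls. That split points to a structure of the samples: its 3 libraries had median mitochondrial shares of 6.44% to 8.53%, the others 22.2% to 32.3%. The share of named epithelial cells parted them the same way, at 1.93% to 5.26% against 18.9% to 86.6%. The mitochondrial and epithelial shares cannot be told apart in that split. The same split gave the highest other count in B cells (73), endothelial cells (23), fibroblasts (73), NK, innate lymphoid or T cells (24), smooth muscle (15) and crypt cells (1), where the real count was 0. The highest other, from other splits, was 2 in absorptive sums, 1 in abundance and 3 for the interaction, against 0. For gene lists the real split gave 60 calls, the highest other 81, and 9 of 10 splits gave as many.

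Only 4 splits exchange the segments within patients, parting all 3 pairs as the real one does, again too few for a share under 0.05. With the patient block, the real labels gave 0 calls but another exchange gave 130 in endothelial cells, 66 in fibroblasts, 41 in smooth muscle, 9 in absorptive and 5 in NK, innate lymphoid or T cells. The 130, the 41 and the 91 of B cells came with the labels of patient 2 exchanged, which points to a structure of the samples in which patient 2 departs from the others. Without patient 2 the real labels gave 671 calls in endothelial cells, 61 in smooth muscle and 69 in B cells, and the only other exchange 0, 1 and 0. Crypt cells gave 3 and the highest other 0 (1 of 4), B cells gave 61 calls and the highest other 91 (2 of 4 as large), abundance gave 3 classes and the highest other 0 (1 of 4), and gene lists gave 64 and the highest other 87 (4 of 4). The other splits exchange the segments of 1 patient each, and without the block they gave at most 0 calls in whole samples, 3 in fibroblasts and 79 lists.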
